A study of Sus scrofa with 9 samples.

How the data were processed

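Bulk RNA sequencing measured transcripts in whole gallbladder of newborn pigs (4 CFTR-/- and 4 CFTR+/+ libraries), and single-cell RNA sequencing measured 1 further CFTR+/+ gallbladder. Per the labels' protocols, bulk libraries were made with an Illumina TruSeq kit from RNA with integrity numbers above a set minimum, and the single cells were scraped from the luminal surface, dissociated with pronase and DNase, separated on an iodixanol density gradient and captured with the 10x Genomics Chromium 3' v3 kit. The labels give each bulk library its own number but do not state that each came from a separate animal, so p-values measure the spread between these libraries.

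The deposited bulk values are estimated counts per Ensembl pig transcript, made by the authors with kallisto 0.45.0 on Sscrofa11.1 per the submitters' processing notes; they divide ambiguous reads among transcripts, so most are not whole numbers. The index release and any trimming are not given in the sources used here. The deposited single-cell matrix holds UMI counts per gene and barcode from Cell Ranger 3.0.2 per the submitters' processing notes, limited to barcodes called as cells per the file labels. It covered 26656 genes and none of the 13 mitochondrial genes sought, so the planned limit of 25% mitochondrial UMIs removed no cell.

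The groups, tests, gene lists, cell type markers, rule for named genes and most of the alternative settings were fixed before the data were examined. The plan was to sum transcripts per gene where a table pairs them with genes. Of the IDs in the files, 0 were paired, so the test ran per transcript, as the plan foresaw. Estimated counts were rounded to whole numbers. Of 46076 transcripts, 35295 passed the filterByExpr filter of edgeR 4.0.16 (R 4.3.3). Counts were scaled with TMM factors and tested with the edgeR quasi-likelihood test on genotype alone, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Levels are TMM-normalised CPM, and log2 fold changes are CF minus non-CF. Alternatives were other scalings (size factors of the DESeq2 kind, upper quartile, library size alone), DESeq2 1.42.0, voom and log2(TPM + 1) in limma 3.58.1 (pseudocount 1), other filters, an effective length offset, the run of title numbers as a term, and leaving out each replicate. The named gene rule asked for symbols and past-threshold genes. With neither, the 2 transcripts with the lowest p in each direction, average CPM of at least 1 and no overlap between groups were named. All splits of the 8 libraries into even groups (35) were refitted. The test was checked on simulated counts for the 35295 transcripts, with 200 changed by known folds. At the estimated dispersion it made 8 false calls, beside 1, 36 and 44 true calls of changes of 1, 2 and 3 log2 units. At a 4-fold lower dispersion it recovered 62.1%, 92.5% and 97% of changes of 1, 2 and 3 log2 units. Bulk replicates of 1 group had a biological coefficient of variation of 0.505.

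Single cells with at least 500 detected genes were kept with scanpy 1.11.5 (Python 3.11.15). Of 2409 barcodes, 933 (38.7%) fell below that minimum. Scrublet marked 6 of the 1476 remaining as doublets (0.407%), which were removed. No label says that doublets had been removed earlier, and doublets that the caller missed stay among the cells. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 30 components, 15 neighbours and Leiden resolution 1 gave 20 clusters. A cluster took a class name where the mean log2 fold of the class's markers against the median cluster was at least 1.5 and at least 3 markers were raised 2-fold. It stayed unnamed where another class's markers were among its 10 leading genes, or where its median UMI count was below 0.5 of the library's median with none of its own markers among those 10. This naming rule was set after a first look at the clusters. The rule left 4 of the 20 clusters unnamed. Leading genes have the largest fold of cluster CPM plus 10 over the rest plus 10. The procedure was run on 1120 cells simulated from the pooled profiles of the 7 classes named in this library. Clustering separated all classes into 8 clusters, named 940 cells rightly and 0 wrongly, and left the rest, among them all 89 endothelial-like cells, unnamed. These cells had no variation within a class beyond counting error, and the profiles came from the same naming rule. The check therefore does not test whether the class names are right. Class levels are CPM of summed UMIs with exact Poisson 95% intervals, shares have Clopper-Pearson 95% intervals, a floor is 3 counts, and all cover counting error only. For shares of cells with a UMI, cells were thinned to 2000 UMIs. Alternatives were minimums of 200 and 1000 genes, doublets kept, Leiden resolutions of 0.5 and 2, another clustering seed, and other treatments of the low-UMI clusters.

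Not run for lack of gene names in the bulk tables were the CFTR level, the camera and fry tests of the 33 gene lists and the single-cell level of bulk calls. The lists were therefore read only across the single-cell classes. Of the genes that the rule named, 1 is not reported here.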

Results

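The series asked how loss of CFTR, the anion channel that carries chloride and bicarbonate across epithelia and that is defective in cystic fibrosis, alters the gallbladder at birth. Bulk RNA sequencing comprised 8 libraries of whole gallbladder from newborn pigs, 4 of genotype CFTR-/- (CF) and 4 of genotype CFTR+/+ (non-CF). The CF libraries held 46.7, 41.6, 51.5 and 59.8 M estimated counts (replicates 1 to 4), and the non-CF libraries 55.7, 55.2, 58.5 and 63.7 M. A single-cell library was made from cells scraped off the luminal face of 1 non-CF gallbladder, so it describes the cells of that scraping and holds no genotype comparison. It comprised 2409 barcodes with a median of 1464 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule).

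The edgeR test called 0 transcripts higher and 0 lower in CF gallbladders among the 35295 tested, while DESeq2 called 298 higher and 538 lower at the same adjusted threshold. The transcripts nearest to the threshold differed several-fold between genotypes. ENSSSCT00000010352.3 averaged 161 ± 76.5 CPM (counts scaled to a common library total; SD, n = 4) in CF and 10.8 ± 3.34 in non-CF libraries, a log2 fold change of 3.89 (SE 0.402, edgeR adjusted p = 0.0878). ENSSSCT00000015539.3 averaged 35.4 ± 2.91 CPM in CF and 7.66 ± 3.18 in non-CF libraries (log2 fold change 2.21, SE 0.277, edgeR adjusted p = 0.146). In the opposite direction, ENSSSCT00000036715.1 averaged 24.4 ± 5.26 CPM in CF and 102.7 ± 9.04 in non-CF libraries (log2 fold change -2.08, SE 0.188, edgeR adjusted p = 0.0582). ENSSSCT00000022966.2 averaged 0.835 ± 0.301 CPM in CF and 7.22 ± 1.62 in non-CF libraries (log2 fold change -3.11, SE 0.36, edgeR adjusted p = 0.146). These 4 transcripts were named by a rule that required no overlap between the groups. The deposited tables pair none of the transcript IDs with a gene, so these transcripts carry no gene names, the fixed gene lists could not be tested between genotypes, and the CFTR level that would check the genotype labels was not analysed here.

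**Figure D1:**
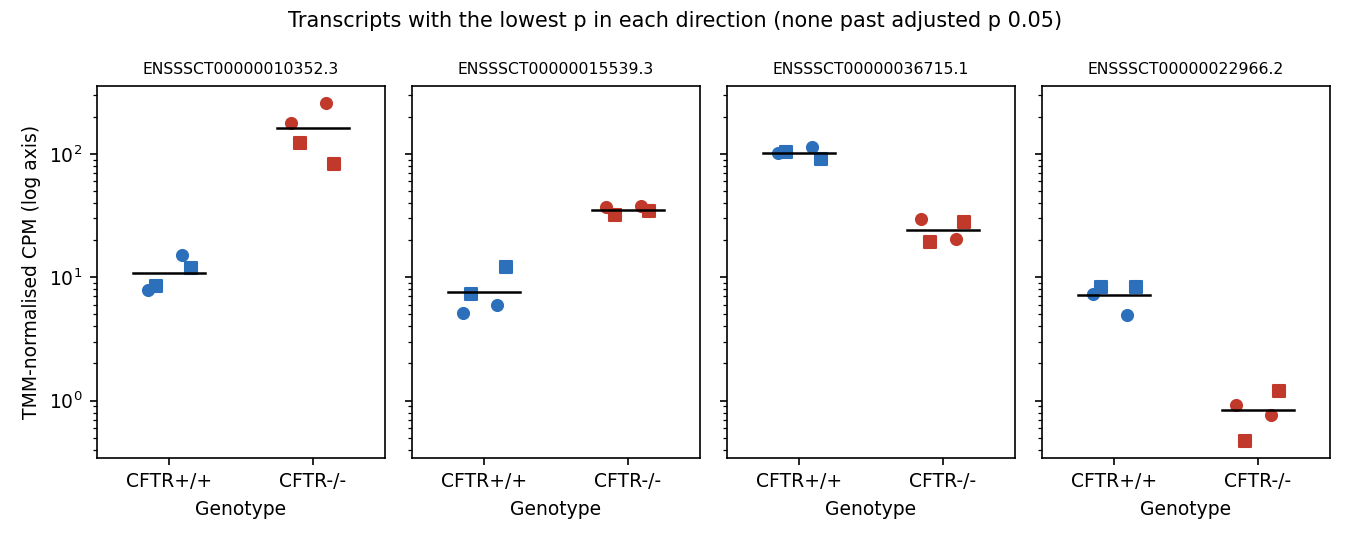
Levels of the 4 named transcripts in each bulk library, as TMM-normalised CPM on a log axis, in CFTR+/+ (blue) and CFTR-/- (red) gallbladders; circles are libraries with title numbers starting 32, squares those starting 33, and lines are group means (n = 4). The transcripts were chosen for the lowest p among those without overlap between groups, and none passed an adjusted p of 0.05 in edgeR.

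At an unadjusted p under 0.05, edgeR gave 1484 transcripts higher and 2402 lower in CF gallbladders, 11% of those tested where 5% would be the average without a difference. Transcripts are not independent, and 4 of the 35 even splits of the 8 libraries, the genotype split included, gave as many. Some of these differ from the genotype split by only 1 exchanged pair of libraries and so hold part of its contrast. The CF and non-CF libraries did not overlap for 2436 transcripts (1001 higher and 1435 lower in CF), or 6.9% where chance gives 2.86% on average. Limma-voom called 1 lower, and limma on log2(TPM + 1) called 4 higher and 4 lower at the same adjusted threshold. The balance between directions depended on the scaling. The median log2 fold change over all tested transcripts was 0.019 with TMM factors, 0.211 with library size alone and 0.162 on log2(TPM + 1), and the unadjusted split became 2713 higher and 1350 lower with library size alone and 2729 higher and 1441 lower on log2(TPM + 1). The unadjusted total of 3886 was 2411 without non-CF replicate 3, 2540 without CF replicate 1 and 6686 without CF replicate 4. In simulated libraries of the same means, depth and spread, the edgeR test recovered 1.5% of transcripts changed by 1 log2 unit, 53.7% of those changed by 2 and 65.7% of those changed by 3. The changed transcripts all averaged at least 1 CPM, and counts were drawn independently without structure among the libraries, unlike in the data.

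The libraries also differed along a line that the genotype does not explain. The libraries' title numbers fall in 2 runs, starting 32 and 33, each with 2 CF and 2 non-CF libraries, and the labels do not say what a run stands for. With genotype in the model, edgeR called 4110 transcripts between the runs (11.6% of those tested), 2315 higher and 1795 lower in the run starting 33. The run accounted for 27.3% of the variance of log2 CPM, the largest share of the 35 possible even splits of the 8 libraries (exact permutation p = 0.0286, the smallest this design allows). The genotype accounted for 18.9%, the rank of 4 among the 35 splits (exact permutation p = 0.114). The 35 splits averaged 14.3%, so a part of each of these shares is what an arbitrary even split takes. Among the 18 splits that keep 2 libraries of each run on each side, the genotype had the largest share (exact permutation p = 0.0556, the smallest those splits allow). With the run as a term, edgeR again called 0 transcripts between genotypes (lowest adjusted p = 0.0825), and 7216 had an unadjusted p under 0.05, while DESeq2 called 1525 higher and 2145 lower and limma-voom 1 in each direction. Correlation across transcripts averaged 0.913 between libraries of the same genotype and run, 0.892 between genotypes within a run and 0.875 between runs within a genotype. No pair of libraries agreed within sampling noise, so none was treated as a library deposited again.

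**Figure D2:**
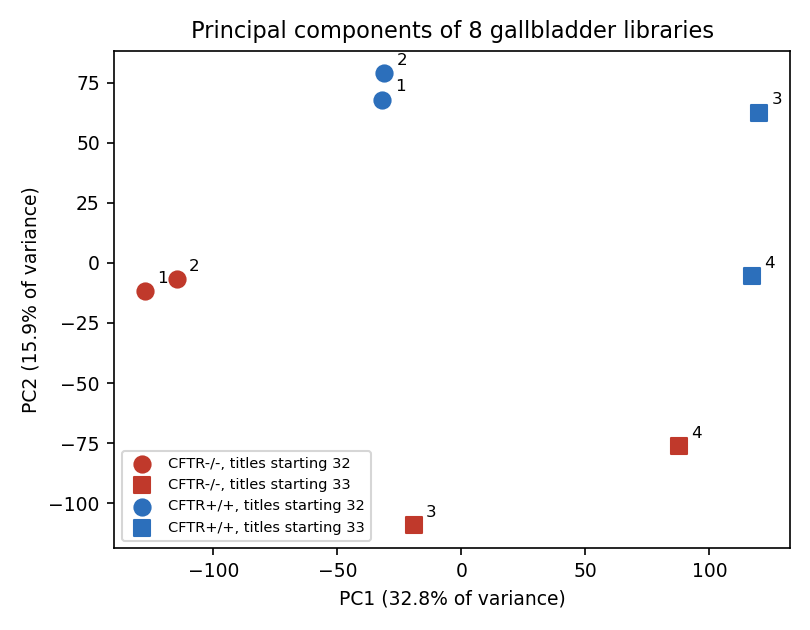
Principal components of log2 CPM for the 8 bulk libraries, PC1 (32.8% of variance) against PC2 (15.9%); color gives the genotype, the marker shape the run of title numbers, and the digit the replicate. The libraries of titles starting 32 lie at negative PC1, those starting 33 at positive PC1 except CF replicate 3. Within each run the CF libraries lie lower than the non-CF libraries on both PC1 and PC2, so PC1 mixes run and genotype.

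The lumen-face scraping of the non-CF gallbladder yielded mostly epithelial cells and leukocytes. Of 1470 cells kept, 483 were epithelial-like (32.9%, Clopper-Pearson 95% interval 30.5 to 35.3%) and 533 belonged to 4 leukocyte classes (36.3%, 33.8 to 38.8%). T or NK-like cells made up 15.9% (14.1 to 17.9%), macrophage or monocyte-like cells 10.8% (9.27 to 12.5%), neutrophil-like cells 7.89% (6.56 to 9.39%) and mast-like cells 1.63% (1.05 to 2.42%). Endothelial-like cells made up 6.05% (4.89 to 7.40%) and fibroblast-like cells 1.497% (0.940 to 2.26%). The remaining 343 cells, 23.3%, lay in 4 clusters left unnamed. Of these, clusters 2 and 6 (266 cells, 18.1%) carried epithelial markers at median depths of 1147 and 1772 UMIs, against 18732 in epithelial-like cells; with them the epithelial share was 50.95%. The ribosomal RNA gene RN18S took 21.6% and 18.5% of the UMIs in clusters 2 and 6, against 1.28 to 3.10% in the epithelial-like clusters. The threshold of UMIs that kept cluster 6 out was set after the data had been seen. The epithelial-like share was 53.2% with cells of at least 200 genes, and the leukocyte share 21.9%, so both shares hold for the gene minimum used as well as for scraping and density separation. There was 1 single-cell library, so no value from it has a replicate check, and the intervals of shares and of CPM (exact Poisson) cover counting error only.

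**Figure D3:**
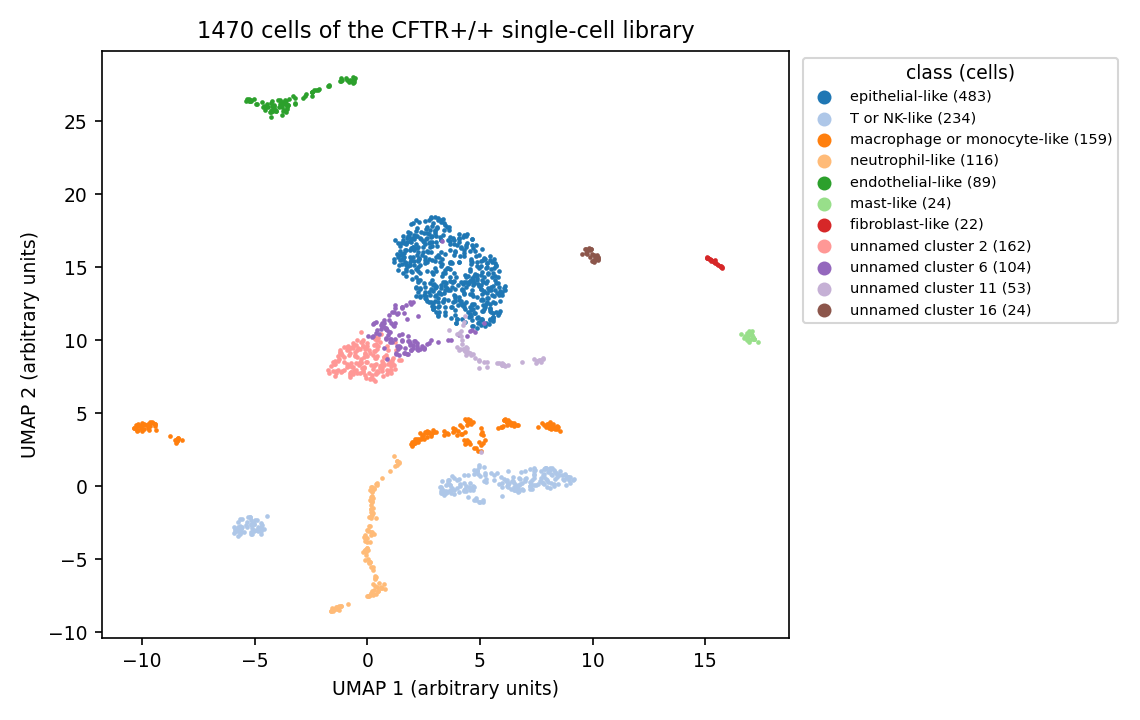
UMAP of the 1470 cells kept from the CFTR+/+ single-cell library (both axes in arbitrary units); each point is a cell, colored by named class or unnamed cluster, with cell numbers in the legend. The 483 epithelial-like cells are the largest class, and the 4 unnamed clusters hold 343 cells.

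CFTR was an epithelial transcript in the non-CF gallbladder. The epithelial-like cells held 992 CFTR UMIs, or 111.5 CPM (104.6 to 118.6), and 350 of the 483 cells had at least 1 (72.5%, 68.3 to 76.4%). Among leukocytes, which serve as the background of free RNA, 6 of 533 cells had a CFTR UMI (1.13%, 0.414 to 2.43%). Median depths were 18732 UMIs in epithelial-like cells and 4444 in leukocytes. After each cell was thinned to 2000 UMIs, 20.7% of the 445 deep enough epithelial-like cells and 0.943% of the 212 T or NK-like cells had a CFTR UMI, with 38 and 22 cells left out. CFTR stood at 100.5 CPM (91.5 to 110.1) in epithelial-like cluster 1, 125.4 (110.4 to 141.9) in cluster 3 and 120.9 (107.2 to 135.9) in cluster 4. The highest level was in the small unnamed cluster 16, at 403.8 CPM (333.7 to 484.3) with a UMI in 21 of 24 cells. FOXI1, the transcription factor of ionocytes, a rare CFTR-rich airway cell type, had 0 UMIs in epithelial-like cells. That count leaves out the unnamed clusters, cluster 16 among them.

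**Figure D4:**
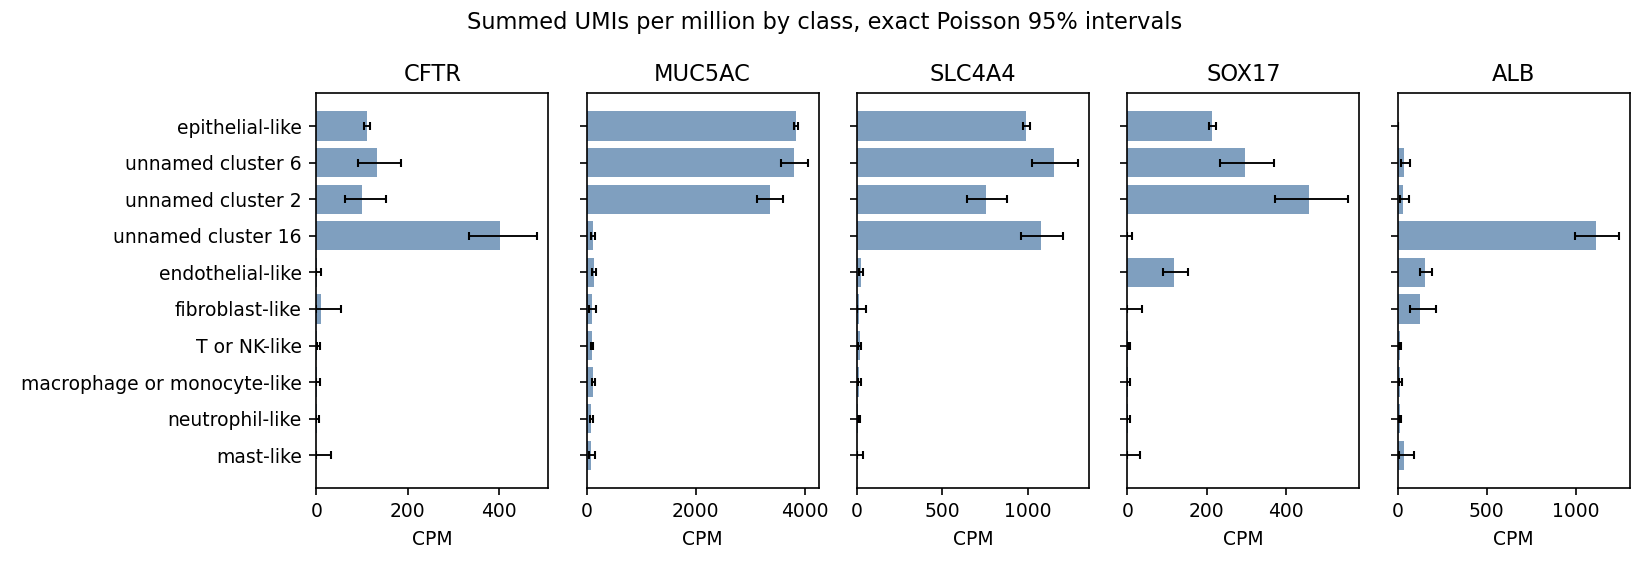
Summed UMIs, as CPM, of CFTR, MUC5AC, SLC4A4, SOX17 and ALB in the named classes and in unnamed clusters 6, 2 and 16 of the single-cell library; bars start at 0 and error bars are exact Poisson 95% intervals of counting error. CFTR reaches 403.8 CPM in cluster 16 and 111.5 CPM in epithelial-like cells, while MUC5AC is 3843 CPM in epithelial-like cells and 107.9 CPM in cluster 16.

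Mucous secretion genes were abundant in the epithelial-like cells. Lists were compared among the named classes only. Of the list of mucins and mucous secretion genes, 21 members had at least 3 UMIs and 17 of them were highest in epithelial-like cells among these classes, where the list summed to 13001 CPM. AGR2, a disulfide isomerase needed for mucin folding, stood at 3984 CPM (3943 to 4026). The gel-forming mucins MUC5AC and MUC5B stood at 3843 CPM (3803 to 3884) and 2553 CPM (2520 to 2586), and MUC5B was higher in the unnamed clusters 2 and 6, with few UMIs and much RN18S, at 9622 and 7191 CPM. The trefoil peptide TFF3 stood at 903.0 CPM (883 to 923), and the membrane mucin MUC1 at 445.1 CPM (431 to 459). In T or NK-like cells, as background, MUC5AC stood at 98.1 CPM (80.8 to 117.9) and AGR2 at 50.3 CPM (38.2 to 65.1). Other secretory genes, chosen after their values were seen, gave 0 UMIs for MUC6, TFF1 and TFF2 in epithelial-like cells, where 3 UMIs would be 0.337 CPM, and 4.50 CPM (3.21 to 6.12) for MUC2.

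Several genes of ion and fluid transport were abundant in epithelial-like cells. Of 25 list members with at least 3 UMIs, 14 were highest in epithelial-like cells, and the list summed to 4735 CPM there. CA4, a membrane carbonic anhydrase, stood at 1099 CPM (1077 to 1121), and SLC4A4, a sodium bicarbonate cotransporter, at 992.1 CPM (971.5 to 1013). ATP1B1, a beta subunit of the sodium pump, stood at 487.2 CPM (472.8 to 501.9). SLC26A3, a chloride bicarbonate exchanger, stood at 428.2 CPM (414.7 to 442.0). Of members chosen after their values were seen, the sodium proton exchanger SLC9A3 stood at 246.4 CPM (236.2 to 257.0) and the water channel AQP1 at 397.0 CPM (384.0 to 410.3). The epithelial sodium channel subunits gave 8 UMIs for SCNN1A (0.899 CPM, 0.388 to 1.77) and 0 for SCNN1B and SCNN1G, and the anion transporter SLC26A9 gave 0 UMIs. A gene with no UMI in a 3' library was not detectable at this depth and with the annotation used, which leaves its absence open.

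Sterol and defence lists were carried partly by epithelial-like cells. In the cholesterol synthesis list 17 of 22 members with at least 3 UMIs were highest in epithelial-like cells, led by HMGCS1 and SQLE, and the list summed to 2127 CPM. In the bile acid and sterol transport list 5 of 17 were, and its sum was 2297 CPM against 3578 CPM in endothelial-like cells, with the apolipoprotein APOA1 at 1887 CPM in epithelial-like and 3167 CPM in endothelial-like cells. The endothelial-like sum rested on cluster 19 (16 cells, 10486 CPM), while cluster 9 (73 cells) summed to 1582 CPM, below the epithelial-like level. The ileal bile acid uptake carrier SLC10A2, the sterol exporters ABCG5 and ABCG8, and FGF19 and FABP6 had 0 UMIs in all named classes. The antimicrobial and mucosal defence list summed to 15350 CPM in epithelial-like and 18504 CPM in neutrophil-like cells (40834, 1855 and 816.3 CPM in neutrophil-like clusters 10, 14 and 20). Its leading epithelial members were the scavenger receptor DMBT1 at 7367 CPM, the immunoglobulin transporter PIGR at 3758 CPM, the protease inhibitor homolog WFDC2 at 2821 CPM and the hydrogen peroxide producing oxidase DUOX2 at 696.1 CPM. All 22 members of the epithelium list, which holds the markers that named the class, were highest in epithelial-like cells among the named classes (14204 CPM). In unnamed cluster 16 EPCAM was 1.40 times (1.23 to 1.59) the epithelial-like level.

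The epithelial-like class fell into 3 clusters, described here by the genes that define them. Cluster 1 (203 cells) was led by the chemokine CCL20, the collagenase MMP13, RND1, the plasminogen activator PLAT and the neutrophil chemokine CXCL8. Cluster 3 (150 cells) was led by the secreted glycoprotein OLFM4, the tight junction protein CLDN10, an unnamed locus, the cobalamin binder TCN1 and FXYD2, a regulator of the sodium pump. Cluster 4 (130 cells) was led by the quinone reductase NQO1, 3 unnamed loci and the aldo-keto reductase AKR1C1. MUC5B, itself 1 of the 15 leading genes of cluster 3, stood at 0.628 times (0.612 to 0.645) the other epithelial-like level in cluster 1. CFTR stood at 0.817 times (0.720 to 0.927) the other epithelial-like level in cluster 1.

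The leukocyte classes covered lymphoid and myeloid cells. The T or NK-like clusters were led by TAC3, LTB, IL7R, IL17F and IL17A in cluster 5 (108 cells), by the chemokine XCL1 and the T cell receptor chains CD3E and CD3G in cluster 8 (75 cells), and by the granzyme GZMA, CCL5 and KLRK1 in cluster 12 (51 cells). Macrophage or monocyte-like clusters were led by lysozyme (LYZ) and the class II genes SLA-DRA, SLA-DQA1, SLA-DQB1 and SLA-DRB1 in cluster 7 (95 cells), by C4BPA, CLEC4F, CD163, C1QA and HMOX1 in cluster 13 (41 cells), and by CALCR, APOE, P2RY12, SLC2A5 and FCGR1A in cluster 17 (23 cells). Neutrophil-like cells ranged from cluster 20 (16 cells; the primary granule genes PRTN3, AZU1, ELANE and MPO) through cluster 10 (60 cells; the secondary granule and cathelicidin genes PR39, NPG4, LTF, PMAP-36 and PGLYRP1) to cluster 14 (40 cells; SDS, C5AR1, TGM3 and PADI4). The inflammatory cytokine and acute phase list summed to 95434 CPM in neutrophil-like cells (7887 CPM in cluster 20, 121296 and 188477 CPM in clusters 14 and 10). It holds S100A8, S100A9 and S100A12, markers that named the class, at 40342, 70403 and 55930 CPM in cluster 10. The neutrophil-like sum was therefore high by construction and is no measure of cytokine transcripts. In epithelial-like cells, where 4 of its 28 members were highest, the list summed to 3051 CPM (4666 CPM in cluster 1, 1295 and 1405 CPM in clusters 3 and 4). The antigen presentation list summed to 25247 CPM in macrophage or monocyte-like and 2823 CPM in epithelial-like cells. The list of B and plasma cells reached no more than 237.2 CPM in any named class, and no cluster was named from B cell markers.

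Stromal classes were small in this scraping. Fibroblast-like cells (22 cells) were led by COL1A1, COL3A1, MGP, COLEC11 and COL1A2, and held the highest sums among named classes of the extracellular matrix list (26186 CPM, against 71.1 in epithelial-like cells) and of the smooth muscle contraction list (7206 CPM, against 193.1). The matrix list shares collagens with the markers that named the class. Endothelial-like cells formed cluster 9 (73 cells; FCN2, STAB2, CLEC3B, CLEC4G and EMILIN1) and cluster 19 (16 cells; IGF2, IL33, NPPC and PECAM1), and held the highest sum among named classes of the interferon response list (3664 CPM, against 2488). The red cell gene HBB stood at 5521 CPM in endothelial-like and 29.3 CPM in epithelial-like cells. Within the endothelial-like class the erythroid list, which holds HBB, summed to 7219 CPM in cluster 9 and 42.5 CPM (5 UMIs) in cluster 19. Mast-like cells (24 cells) were led by MCT7, MS4A2 and FCER1A. Unnamed cluster 11 (53 cells) mixed 15 cells with at least 5 UMIs of HBB or AHSP and 8 cells with at least 5 UMIs of ACTA2. Unnamed cluster 16 (24 cells) was led by the plasma protein genes TF, AHSG, VTN and FGG and by ANKRD1, while EPCAM stood at 915.6 CPM and KRT19 at 2287 CPM.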

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

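The tests of hepatocytes and of doublets, those of the title-number runs, and the edgeR counts over other splits were chosen only after the result was seen. The tests of sinusoidal endothelium, Kupffer cells and intrahepatic bile duct, and the DESeq2 counts over splits, were chosen before their own values were read, though after the clusters and runs had been seen.

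Transcript levels followed the runs of title numbers. The split by run, which comes from the labels, called 844 transcripts in edgeR without other terms, and the highest other of the 35 splits called 15. Thus 1 of the 35 gave as many, the run split itself. This is the smallest share the design allows, in a test chosen after the pattern was seen, so it does not exclude chance. The next split was closer in other counts: 7714 against 9114 at an unadjusted p under 0.05 in edgeR, and 3294 against 5529 calls in DESeq2. At an equal depth of 41.6 M counts per library, 3975 transcripts were called between runs with genotype in the model, against 4110 at full depth. The 16 transcripts that make up the 10 most abundant of each library took 7.85 to 13.5% of the counts, which allows a shift of 0.0919 log2 units in the others between libraries. The 4107 others called had absolute log2 fold changes of at least 0.383. This comparison cannot decide, since folds as small as the shift could hardly be called at this spread and TMM factors had already removed such shifts. With library size alone, 4761 transcripts were called between runs without those 16, against 4896 with them. Most run calls were thus made without unequal depth and without the abundant transcripts. A shared litter, day or library batch stays open and untested, since the labels do not say what a run is, and no biological explanation was tested.

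Counts of transcripts between genotypes were set against the same splits. In edgeR 0 transcripts passed, a count that 35 of the 35 splits reach by construction, so it says nothing of chance; the highest other was the split by run with 844. At an unadjusted p under 0.05 edgeR gave 3886 transcripts and 4 of the 35 splits gave as many, the highest other being the split by run with 9114. DESeq2 called 836 transcripts and 4 of the 35 splits gave as many, the highest other again being the split by run with 5529. Chance is not excluded for the unadjusted edgeR count or the DESeq2 count, and the run split points to a structure of the samples. The remaining splits that reached these counts differ from the run split by 1 exchanged pair of libraries. Each also differs from the genotype split by 1 exchanged pair, so they hold part of both contrasts and are not free of a genotype difference. Among the 17 other splits with 2 libraries of each run on each side, the highest gave 2147 in edgeR and 67 in DESeq2, though 18 splits are too few for a share under 0.05. With the run as a term the same 18 splits apply: edgeR gave 7216 transcripts at an unadjusted p under 0.05, 1 of the 18 splits gave as many and the highest other gave 4133, and DESeq2 called 3670, again in 1 of 18 splits, with 452 in the highest other.

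The genotype effect differed between the runs for 3 transcripts in an edgeR interaction test (adjusted p = 0.0263, 0.0264 and 0.0316), with 3149 at an unadjusted p under 0.05. These 3 transcripts were singled out after their values were seen, and their IDs are paired with no gene. Each genotype had only 2 libraries per run. The first averaged 0 CPM in the non-CF libraries of the run starting 33. The second averaged 0.181 CPM in the CF libraries of the run starting 32. The log2 ratios of CF to non-CF CPM of the 3 transcripts, each CPM plus 1, were 0.68, -3.36 and -1.95 in the run starting 32. They were 3.87, 0.40 and 2.35 in the run starting 33.

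Barcodes left out for under 500 genes held signal of several cell types, where 3 counts would be 4.24 CPM. HBB stood at 91357 CPM (2061 in kept cells), the ribosomal RNA gene RN18S at 199030 CPM (25931), KRT19 at 1136 CPM (2355) and CFTR at 49.4 CPM (85.0). HBB exceeded 10% of the UMIs in 42 of these barcodes and RN18S in 641.

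Cells with genes typical of liver sinusoids appeared in the single-cell library. In the STAB2-high cluster 9 (73 cells), the detected genes of a sinusoidal endothelium list that leaves out the cluster's leading genes had a median log2 fold of 4.26 against the other 16 endothelial-like cells. Of the 3 detected among 8 list genes, RSPO3 (12.3 CPM) lay under the 25.5 CPM that 3 counts make in the other cells, so the pattern rests on DNASE1L3 (548.0 CPM against 0, at least 21.5-fold higher by that floor) and GPR182 (344.0 against 8.50 CPM, ratio 40.5, 7.14 to 1609), with a median of 5.03 over these 2. In the CLEC4F-high cluster 13 (41 cells) the detected genes of a Kupffer cell list had a median log2 fold of 2.75 against the other 118 macrophage or monocyte-like cells, from 5 of 8 genes led by HPGD (561.8 CPM against 46.5), VSIG4 (379.1 against 47.7), which the macrophage list also holds, and SLC40A1 (365.5 against 23.9). PLVAP, a member of the endothelium list, was also among the leading genes of cluster 13 (3534 CPM against 29.8 in all other kept cells). Mixed cells or doublets with endothelial cells were not tested there. As a hypothesis, liver cells may have entered the scraping, which no sort would have removed, while vessels and macrophages of the gallbladder wall with the same genes stay open and no explanation by genotype was tested.

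Cluster 16 (24 cells) combined the highest CFTR level of the library with ALB at 1114 CPM, TF at 3610 CPM and AHSG at 4459 CPM. For hepatocytes the values were mixed. The median over the 18 genes of the hepatocyte list was 36.6 CPM. It was 165.4 CPM over the 12 with a UMI in the cluster, which leaves out FGA, FGB, CPS1, CYP2E1, CYP3A29 and TAT at 0 UMIs. FGG (675.4 against 2.81 CPM in epithelial-like cells) and APOH (257.6 against 1.12) were raised, and SERPINA1 (765.9 against 917.0) was not. Outside the list, the plasma protein gene VTN (856.4 against 4.06 CPM in all other kept cells) and AMBP (591.8 against 8.27) were raised too. Both are leading genes of the cluster and thus high by definition. EPCAM stood at 1.40 times (1.23 to 1.59) and KRT19 at 0.672 times (0.621 to 0.726) the epithelial-like level, and 21 of 24 cells had a CFTR UMI. These 3 genes argue against hepatocytes as the whole of the cluster. A part of them in it stays open, since no hepatocytes were measured here to give the level they would need. Doublets of an epithelial-like cell with a cell of another named class are argued against by CFTR. It stood at 3.62 times (2.96 to 4.39) the epithelial-like level, and mixing with these CFTR-poorer classes would lower it. Doublets that hold another CFTR-rich cell, such as a bile duct cell with a hepatocyte, were not tested. The cells may come from bile ducts inside the liver: SOX17, a regulator of gallbladder and extrahepatic duct fate, had 0 UMIs in the cluster against 1907 UMIs (214.3 CPM) in epithelial-like cells, a ratio of at most 0.0600 by its 95% interval. The SOX17 count cannot tell duct cells from hepatocytes, in which no SOX17 level was measured here. Another epithelial cell of the gallbladder without SOX17 stays open.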

How the results depend on the processing

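The fits on transcripts with whole counts, DESeq2 and voom with the run as a term, the fits within each run and the last 2 counts of epithelial-like cells were chosen after the data were seen. The balance of transcripts at an unadjusted p under 0.05 turned with the scaling, from 1484 higher and 2402 lower with TMM to 2713 and 1350 with library size alone and 2729 and 1441 on log2(TPM + 1). The 4 named transcripts kept their direction under each alternative that could be fitted (log2 fold changes of 3.33 to 4.25, 1.75 to 2.77, -2.18 to -1.82 and -3.33 to -2.27), and passed the threshold in 4, 4, 6 and 3 of them (adjusted p up to 0.4, 0.464, 0.4 and 0.44 in the others). The 0 transcripts called higher and 0 called lower by edgeR became 298 and 538 with DESeq2, 4 and 4 with limma on log2(TPM + 1), and 1525 and 2145 with DESeq2 and the run as a term. Limma-voom gave 1 lower, or 1 higher and 1 lower with the run as a term, the filter of CPM of at least 1 in 4 libraries gave 1 lower, and the 4105 transcripts with estimated counts within 0.000001 of a whole number in all libraries gave 1 higher. All 836 DESeq2 calls had the same direction and an unadjusted p under 0.05 in edgeR, 747 had no overlap between groups, and 7578 transcripts had no adjusted p in DESeq2. The 3886 transcripts at an unadjusted p under 0.05 became 7216 with the run as a term in edgeR, 8541 so in DESeq2, 7781 so in limma-voom, 7669 in the run starting 32 alone, 3182 in the run starting 33 alone and 747 of the 4105 with whole counts. Leaving out 1 replicate gave 0 calls each time and 2411 (without non-CF replicate 3) to 6686 (without CF replicate 4) at an unadjusted p under 0.05, and 2540 without CF replicate 1. The causes were not tested, except that fewer transcripts were tested under the filters. The labels pair no CF with a non-CF library; the run as a term is the blocked fit.

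The single-cell library gave 2367 cells with at least 200 genes (epithelial-like 53.2%, leukocytes 21.9%) and 1039 with at least 1000 genes (43.4% and 31.0%). The epithelial-like share was 50.95% with the low-UMI clusters counted in and 39.9% with the UMI minimum for a name at 1/3 of the median. Doublets kept, Leiden resolutions of 0.5 and 2 and another seed moved it to 31.4 to 34.0%, inside its interval. CFTR stood at 110.9 to 112.1 CPM in epithelial-like cells over all 8 alternatives. Not run were the CFTR level, camera with a preset or estimated correlation, fry and the single-cell level of bulk calls, for which the transcripts needed genes, the transcript-level alternative, which became the test itself, and the 10% and 50% mitochondrial limits, since the matrix holds no mitochondrial gene. Depth sets the floor of 3 UMIs at 0.337 CPM in epithelial-like and 29.3 CPM in fibroblast-like cells.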

Other observations

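The genes in this part were chosen after their values were seen. AFP, the fetal albumin-like plasma protein, stood at 4876 CPM (4830 to 4922) in epithelial-like cells, with 4232, 5341 and 5732 CPM in clusters 1, 3 and 4, and at 41.7 to 117.3 CPM in the other named classes. In the same cells ALB stood at 2.59 CPM. SPP1, the secreted phosphoprotein osteopontin, stood at 15426 CPM (15344 to 15507), and MMP7, a matrix metalloproteinase of secretory epithelia, at 10127 CPM (10061 to 10193). In cluster 16 AFP was 0.226 times (0.201 to 0.252) the epithelial-like level and MUC5AC 0.0281 times (0.0191 to 0.0399), while SLC4A4 was 1.09 times (0.968 to 1.22). That cluster also held APOA1 at 11812 CPM, CXCL8 at 2837 CPM and the complement gene C3 at 1368 CPM.

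Among lists not described with the comparisons, oxidative phosphorylation summed highest among the named classes in epithelial-like cells (3690 CPM; 9 of 16 members with at least 3 UMIs highest there). The unfolded protein response list summed to 5925 CPM in epithelial-like and 7885 CPM in endothelial-like cells. Oxidative stress response genes summed to 23642 CPM in epithelial-like and 28053 CPM in macrophage or monocyte-like cells. The immediate early list stood at 21091 CPM in fibroblast-like and 7564 CPM in epithelial-like cells, led by JUN. Cell cycle genes summed to 309.2 CPM in epithelial-like and 1681 CPM in neutrophil-like cells, with 2044, 127 and 1580 CPM in neutrophil-like clusters 10, 14 and 20, of which cluster 20 (16 of the 116 cells) held 433653 of the class's 887231 UMIs. Mesothelium, adipocyte and pancreatic exocrine lists reached no more than 34.3, 29.3 and 8.43 CPM in any named class.

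Transcript length went with the direction of the genotype difference in bulk. The median length was 4234.5 bases for transcripts higher in CF at an unadjusted p under 0.05 in edgeR, 2799 bases for those lower and 3312 bases for all tested. Across transcripts, which are not independent replicates, the rank correlation of length with log2 fold change was 0.118, and 0.096 and 0.107 within the runs starting 32 and 33.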
